A study of Homo sapiens with 8 samples.

How the data were processed

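Poly(A) RNA from the human gastric carcinoma line SNU-638 was sequenced in 8 libraries, 2 in each of 4 groups. The groups were unedited cells (WT), cells lacking miR-221 (221KO), cells lacking miR-222 (222KO) and cells lacking both microRNAs (DKO), with group and replicate number taken from the sample titles and the genotype labels. The labels do not say whether the libraries of a group came from separate cultures or clones, nor how the loci were edited. RNA was extracted with TRIzol and enriched with oligo(dT) beads, and libraries were made with a TruSeq Stranded kit, per the labels' protocols. STAR and Cufflinks, without versions or roles, and the genome build GRCh37 (hg19) are named per the submitters' processing notes; the annotation version and the settings were not given in the sources used here. The authors deposited 1 table of FPKM values (fragments relative to transcript length and library total) for 53216 RefSeq transcripts, 41427 of them with coding accessions and 11789 with noncoding accessions. Of these transcripts, 3304 were placed more than once in the genome. FPKM divides by transcript length and library total, so a gene that takes a large share of a library lowers the values of the rest, and transcripts shorter than a fragment receive very high values from few fragments.

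Transcript values were summed to 26249 gene symbols. Fragment numbers were not used for testing. Library scales were read from single-transcript genes with FPKM under 0.5 in every library. Of their values above 0 in both, 14.5% to 20.2% lay near 1 common ratio to WT replicate 1 (bin width 0.002 in ln). On this scale the lowest value of a gene above 0 was taken as a step of 1 fragment. Depth used 220 single-transcript genes of 2000 to 4000 nt, chosen for having 3 or more libraries at that step (relative tolerance 0.003). Their steps gave estimated totals of 29800000 and 29000000 fragments for WT, 31300000 and 29600000 for 221KO, 30200000 and 31600000 for 222KO and 30300000 and 27500000 for DKO. The hairpin entries MIR221 and MIR222 were put on the library scale of these steps. The smallest MIR222 value above 0 was then taken as 1 fragment, and both entries as equally long. On that assumption 16 of 16 values came out within 0.1 of a whole number, but the MIR222 zeros and the smallest value itself are whole by construction. At these totals a transcript with few fragments changes by whole steps, so short entries are imprecise.

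Differences were tested with limma on log2(FPKM + 1) for 12588 genes with a mean FPKM of at least 1 over the 8 libraries, 606 of them small RNA entries, with values as deposited and no further scaling. One model held all 4 groups, which shared 1 estimate of the spread (4 residual degrees of freedom, prior degrees of freedom 1.72), without trend or robust options. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The comparisons were each knockout with WT, the knockouts with each other, and the interaction (DKO minus 221KO minus 222KO plus WT). A fold change is on the log2(FPKM + 1) scale and understates the change of low genes. p-values measure only the spread between these libraries, which may be technical. Analyses used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and R 4.3.3 with limma 3.58.1.

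Gene lists were written from general knowledge: literature targets of the microRNAs, neighbours of their locus, G1/S and G2/M genes, p53 targets, the BCL2 family, NF-kB, interferon, major histocompatibility complex class I, mesenchymal and epithelial genes, cholesterol synthesis, glycolysis and hypoxia, the unfolded protein and integrated stress responses, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, immediate early genes, YAP, WNT, TGF-beta and FOXO targets, microRNA machinery, metallothioneins, NRF2 targets and histones. They named 824 members, 805 of them in the table. The 25 lists with at least 5 tested genes entered limma's camera with a preset correlation of 0.01, and again with an estimated correlation, with fry beside it; Benjamini-Hochberg adjustment ran over the lists of a comparison. Marker genes of leukocytes, red cells, fibroblasts and endothelial cells were used only as a check for other cell types.

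Named genes were the 10 that rose and the 10 that fell most on the log2 scale against WT, among those past the threshold with a mean FPKM of at least 5, both knockout libraries on the same side of both WT libraries, and no systematic name. For 221KO against 222KO and for the interaction the rule took 5 per direction without the condition on sides. Known targets, the hairpins, the locus neighbours and up to 4 members of lists with a call were named whatever their values, except 1 known target that is not reported here. The rule also named small RNA entries: 8 in 221KO, 8 in 222KO and 9 in DKO against WT, 5 in 221KO against 222KO and 8 in the interaction. All 13 such entries other than the 2 hairpins held whole multiples, within 0.1, of their own smallest value on the one-fragment scale, and 11 of the 13 never exceeded 3 multiples. The genes described below were therefore taken by the same rule with small RNA entries passed over, a choice made after the values were seen. Genes named for DKO against 221KO and genes detected in some groups alone, counted without small RNA entries, were also chosen after the values were seen.

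Sites for the shared seed of miR-221-3p and miR-222-3p were searched in the longest annotated 3' UTR of each gene in GENCODE 29 (GRCh38), with 18745 genes of the table matched by RefSeq accession or symbol. A site was either of the 7-base forms ATGTAGC and TGTAGCA, and permuted sites were searched in the same way. Positions given here are on GRCh38 and were not combined with positions on the build of the deposited table. The median log2 change of genes with a site was compared with that of genes without one, with camera adjusted over all 27 site tests, and ranked among all 630 distinct permutations of the 7 bases of the site. Pairing beyond the seed was read from the 4 bases complementary to nucleotides 13 to 16 of each microRNA, starting 6 to 12 bases upstream of the site, with a two-sided permutation test of 100000 resamples. For comparisons against the same WT libraries, 100 simulated experiments without any effect gave the overlap and covariance that shared controls produce, and 100 more with 1 library fewer gave the correlation for a knockout left with 1 library.

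The comparisons, lists, rule for named genes and most alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at FPKM 5, median-of-ratios scaling, quantile normalization, a replicate block, trend and robust options, a 1.5-fold limit, a fit of the 2 groups compared alone, and leaving out each library. Leaving out small RNA entries, averaging the 222KO libraries to 1, separate WT libraries for the overlap of knockouts, and other limits for genes detected in WT only were chosen after seeing the data. When a group was left with 1 library, that library was assumed to vary like those of the other groups. On simulated data over the 12588 genes with 200 genes changed in DKO against WT, the limma step recovered 83.5% of changes of log2 1 with 3 false calls and 94.0% of changes of log2 2 with 12 false calls. The seed step, on simulated values for 11203 genes with a shift of 0.1 in DKO against WT, returned 0.104 at rank 1. With no change put in, it returned 0.00445 at rank 74 in 221KO against WT.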

Results

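The study asked which functions the paralogous microRNAs miR-221 and miR-222 share and which are specific to each. Both lie on the X chromosome, carry the same seed and were removed singly or together in SNU-638, an established human gastric carcinoma cell line. Messenger RNA was measured as FPKM in 2 libraries each of WT, 221KO, 222KO and DKO cells (n = 2 throughout, errors are SD). Estimated depth ranged from 27500000 fragments in DKO replicate 2 to 31600000 in 222KO replicate 2, and 12092 to 12354 genes per library reached an FPKM of 1. Libraries of 1 group correlated across genes with r = 0.940 in WT, 0.931 in 221KO, 0.942 in 222KO and 0.929 in DKO; genes are not independent replicates. The 222KO libraries lay closest together, with a median absolute log2 difference of 0.07 against 0.15 in WT, 0.19 in 221KO and 0.16 in DKO. Their squared differences were 1.26, 1.77 and 3.53 times counting noise at 50 to 200, 200 to 1000 and 1000 to 5000 fragments. Values above counting noise arise also between 2 preparations of the same RNA, so they do not show separate cultures. The pair was entered as 2 libraries as labelled, and counts with it averaged to 1 stand beside the comparisons with WT, the other knockouts and the interaction. On the first principal component (28.1% of the variance) WT lay at −53.0 and −35.1, 222KO at −5.29 and −6.07, 221KO at 10.7 and 32.5, and DKO at 18.4 and 37.9. On the second (16.3%), replicates 1 of 221KO and DKO lay at −13.9 and −2.98 and replicates 2 at 19.6 and 21.9, so on both components these 4 libraries separated by replicate and not by group.

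The targeted hairpins were read first. MIR221 (chromosome X, 45746157 to 45746266, minus strand, GRCh38) and MIR222 (45747015 to 45747124) lie inside the annotated noncoding host gene MIR222HG (45745211 to 45770274), whose own transcript was not analysed here. The MIR221 entry held 9 and 6 fragments in WT, 188 and 215 in 221KO, 25 and 22 in 222KO and 297 and 368 in DKO. It rose by 4.70 ± 0.243 (SE) on the log2 scale in 221KO (adjusted p = 0.000338), by 1.59 in 222KO (adjusted p = 0.0204) and by 5.50 in DKO (adjusted p = 0.000185). The 221KO value lay 3.11 above that of 222KO (adjusted p = 0.00452). MIR222 held 0 and 0 fragments in WT, 1 and 0 in 221KO, 3 and 2 in 222KO and 2 and 4 in DKO; the DKO difference passed (adjusted p = 0.0397) and those of 222KO (0.0599) and 221KO (0.361) did not. Poly(A) RNA over these short hairpins does not measure the mature microRNAs, so it checks neither their loss nor the labels. The MIR221 call in 222KO was lost without WT replicate 1 (adjusted p = 0.0538), WT replicate 2 (0.0834), 222KO replicate 1 (0.146) or 222KO replicate 2 (0.12), and when the 222KO libraries were averaged (0.131). The MIR222 call in DKO, which rests on 6 fragments, was lost without WT replicate 1 (0.176) or 2 (0.133), DKO replicate 1 (0.106) or 2 (0.169), or either 222KO library (0.0937).

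**Figure D1:**
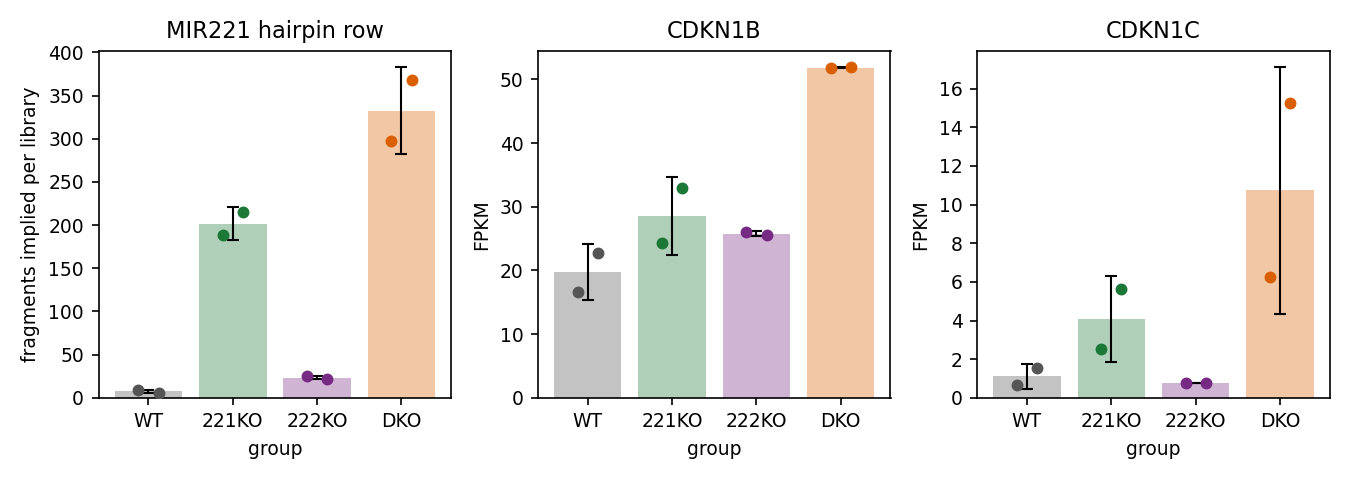
Bars are means, error bars are SD and points are the 2 libraries of each group, for fragments on the MIR221 hairpin (left) and FPKM of CDKN1B (middle) and CDKN1C (right). MIR221 fragments ranged from 6 to 9 in WT and from 297 to 368 in DKO, and CDKN1B averaged 19.7 FPKM in WT and 51.8 FPKM in DKO.

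Of the messenger RNAs long known as targets of both microRNAs, CDKN1B, which encodes the cell cycle inhibitor p27, averaged 19.7 ± 4.33 FPKM in WT, 28.6 ± 6.12 in 221KO, 25.8 ± 0.36 in 222KO and 51.8 ± 0.061 in DKO. It rose in DKO by a log2 change of 1.37 (adjusted p = 0.0111), whereas the differences of 0.51 in 221KO (0.153) and 0.38 in 222KO (0.283) did not pass. DKO also exceeded 222KO by 0.98 (adjusted p = 0.0426) but not 221KO (0.85, adjusted p = 0.359), and the interaction was 0.47 (adjusted p = 0.435), so a departure from additivity was not shown. CDKN1C, which encodes the related inhibitor p57, rose in DKO from 1.11 ± 0.636 to 10.7 ± 6.37 FPKM (log2 change 2.40 ± 0.482 SE, adjusted p = 0.0324). It averaged 4.08 ± 2.22 FPKM in 221KO (adjusted p = 0.172) and 0.777 ± 0.00621 in 222KO (adjusted p = 0.845), and DKO exceeded 222KO by 2.61 (adjusted p = 0.0381). In GRCh38, CDKN1B (chromosome 12, 12715058 to 12722371, plus strand) carries the 8-base site ATGTAGCA in its 3' UTR at 12721228 to 12721235 and 12721301 to 12721308, and CDKN1C (chromosome 11, minus strand) at 2883828 to 2883835. The CDKN1B call in DKO was lost without WT replicate 1 (adjusted p = 0.0599), DKO replicate 1 (0.0635) or DKO replicate 2 (0.0631) and with only WT and DKO in the model (0.0621; range over all alternatives 0.00391 to 0.0635). The CDKN1C call was lost without WT replicate 1 (0.17) or 2 (0.0833), DKO replicate 2 (0.111) or either 222KO library (0.0845), with only WT and DKO in the model (0.113), and without the filter (0.0524; range 0.0104 to 0.17). Against 222KO, the CDKN1B call was lost without 222KO replicate 1 (0.224) or 2 (0.247), DKO replicate 1 (0.161) or 2 (0.163) or either WT library (0.0524). That of CDKN1C was lost without 222KO replicate 1 (0.217) or 2 (0.221), DKO replicate 1 (0.0524) or 2 (0.131) or either WT library (0.0759).

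KIT, the stem cell factor receptor, was listed at 0 in every library, and TIMP3, a metalloproteinase inhibitor, averaged 0.0502 FPKM in WT and was listed at 0 in the knockouts. BBC3, BMF, FOXO3, DDIT4, TRPS1, PIK3R1 and ICAM1, which encode regulators of apoptosis, survival signalling, transcription and adhesion, did not pass against WT in any knockout. Of the 31 tested literature targets, 5 rose and 2 fell in DKO (6 and 2 adjusted over the list alone), 2 rose in 222KO (1 adjusted over the list alone) and 1 rose in 221KO (0 adjusted over the list alone). ETS1, a transcription factor, was the gene that rose in all 3, from 74.2 ± 5.13 FPKM in WT to 101 ± 4.77 in 221KO, 103 ± 2.86 in 222KO and 103 ± 1.93 in DKO (adjusted p = 0.029, 0.0286 and 0.0214). The list as a whole did not pass in 221KO, 222KO or DKO (adjusted p = 0.389, 0.85 and 0.107). Of 7 tested neighbours of the microRNA locus, KDM6A, a histone demethylase, rose in 221KO (log2 change 0.44, adjusted p = 0.0206) and in DKO (0.38, 0.0285) and did not pass in 222KO (0.30, 0.0659). The other 6, CHST7, FUNDC1, KRBOX4, RP2, SLC9A7 and ZNF674, did not pass, and the list did not pass in any knockout (adjusted p = 0.824, 0.659 and 0.912). The calls of ETS1 were each lost without WT replicate 1, with adjusted p of 0.07 in 221KO, 0.0717 in 222KO and 0.0578 in DKO, or WT replicate 2 (0.0936, 0.0982 and 0.0763). Those of KDM6A were also lost without WT replicate 1 (0.0875 in 221KO and 0.101 in DKO) or 2 (0.0794 and 0.0954). Both genes also lost calls without single libraries of 222KO or of the knockout compared, at adjusted p up to 0.186.

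Loss of miR-221 alone was compared with WT. The epidermal growth factor receptor ligand EREG fell from 97.1 ± 19.6 to 0.169 ± 0.0509 FPKM (log2 change −6.38 ± 0.157 SE, adjusted p = 1.67e-05), and ALDH1A3, an enzyme of retinoic acid synthesis, from 372 ± 15.4 to 9.47 ± 2.78 (−5.18, adjusted p = 7.9e-05). The actin-bundling proteins LCP1 (53.4 ± 5.33 to 0.185 ± 0.00739) and PLS3 (44.9 ± 3.91 to 1.41 ± 0.107) fell by 5.52 and 4.25. TFPI, an inhibitor of coagulation, fell from 67.4 ± 1.55 to 0.929 ± 0.019, and the calcium-binding protein CALB1, TM4SF19 and the embryonic globin HBE1 fell by 5.05, 5.18 and 5.67. OR51B5, an olfactory receptor gene whose annotation overlaps HBE1 so that their fragments are uncertain, fell by 5.28, and the host transcript MIR100HG, at 31.8 ± 3.34 in WT, was listed at 0 in both 221KO libraries. In the other direction the protease inhibitor SPINK6 rose from 0.770 ± 0.205 to 111 ± 62.7 FPKM (5.87 ± 0.529 SE, adjusted p = 0.0033). MSN (moesin, which links actin to the membrane) rose from 0.592 ± 0.0161 to 93.5 ± 22.8 (5.87 ± 0.235 SE, adjusted p = 0.000116). The serine protease KLK5 rose by 2.94, and the interferon-induced genes IFIT1 (5.79 ± 1.88 to 51.5 ± 12.5), OASL (4.61 ± 1.71 to 44.6 ± 17.6) and IFI6 (21.6 ± 13.6 to 228 ± 125) by 2.96, 3.00 and 3.37. The acute phase genes SAA1 and SAA2, near-identical copies whose fragments are uncertain, rose by 3.87 and 3.15, NNMT, a methyltransferase of nicotinamide, by 3.72, and the calcium-binding protein S100A4 by 2.91.

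Of 37 interferon response genes, 24 rose and 0 fell in 221KO (34 and 0 adjusted over the list alone), with a median log2 change of 1.45. IFI44 rose from 22.3 ± 3.16 to 88.9 ± 7.05 FPKM (adjusted p = 0.000512), HERC6, a ubiquitin ligase, by 1.91 (0.00127) and the RNA sensor DDX58 by 1.92 (0.00458). camera gave adjusted p = 8.31e-18 for the list, and adjusted p = 0.68 with an estimated correlation. The 46 G1/S genes had a median log2 change of −0.36, and 1 member, the replication-linked gene CDCA7, fell (47.5 ± 0.281 to 29.6 ± 2.03; 1 adjusted over the list alone). camera gave adjusted p = 0.000141, and adjusted p = 0.68 with an estimated correlation. Of 25 cholesterol synthesis genes 5 fell (7 adjusted over the list alone; median −0.28; camera adjusted p = 0.000267, and adjusted p = 0.68 with an estimated correlation), among them FDFT1, squalene synthase, from 130 ± 15.9 to 49.3 ± 9.76. Of 27 p53 targets 6 fell (8 adjusted over the list alone; median −0.21; camera adjusted p = 0.0015, and adjusted p = 0.6 with an estimated correlation), among them the DNA damage binding protein DDB2, from 65.2 ± 8.28 to 32.4 ± 0.446.

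Of 15 NRF2 targets, 3 fell and 1 rose in 221KO (7 and 1 adjusted over the list alone; median −0.30; camera adjusted p = 0.00952, and adjusted p = 0.6 with an estimated correlation). The quinone reductase NQO1 fell from 72.7 ± 5.31 to 24.3 ± 3.25 and the cystine transporter SLC7A11 from 6.54 ± 1.48 to 1.07 ± 0.419, while HMOX1, haem oxygenase, rose by 0.79. Of 11 histone genes, which are near-identical copies and uncertain, 2 rose (3 adjusted over the list alone; median 0.59; camera adjusted p = 0.00105, and adjusted p = 0.68 with an estimated correlation), among them HIST1H2BK (16.5 ± 1.45 to 35.1 ± 4.31). Of 5 metallothioneins, also close copies, 1 rose (2 adjusted over the list alone; median 0.30; camera adjusted p = 0.0295, and adjusted p = 0.68 with an estimated correlation), MT1F, by 1.01. Of 28 genes of the unfolded protein and stress responses, 3 fell and 1 rose (3 and 1 adjusted over the list alone; median −0.16; camera adjusted p = 0.0185, and adjusted p = 0.68 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, fell from 14.0 ± 1.2 to 0.0085 ± 0.0121 FPKM. Of 41 oxidative phosphorylation genes, 2 fell (1 adjusted over the list alone; median −0.12; camera adjusted p = 0.0359, and adjusted p = 0.68 with an estimated correlation), among them the complex I subunit NDUFS1, by 0.53.

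limma called 1297 genes in 221KO against WT, 585 higher and 712 lower, of which 359 and 435 changed at least 1.5-fold. The count was 357 without WT replicate 1, 515 without WT replicate 2, 548 without 221KO replicate 2, 473 without either 222KO library or with these averaged to 1, and 160 with only WT and 221KO in the model. Calls of SAA2, NNMT, S100A4, SAA1 and IFI6 were lost without WT replicate 1 (adjusted p = 0.217, 0.217, 0.138, 0.0958 and 0.0869), 221KO replicate 2 (0.166, 0.0933, 0.0737, 0.0759 and 0.0741) or either 222KO library (0.109, 0.108, 0.071, 0.0555 and 0.0609). Those of SAA2, NNMT and S100A4 were also lost without WT replicate 2 (0.126, 0.116 and 0.068). Calls of CDCA7 and FDFT1 were lost without WT replicate 1 (0.0695 and 0.0583) or 2 (0.0558 and 0.0671), and MT1F without WT replicate 1 (0.0567). NDUFS1 and HMOX1 lost theirs without either WT library (0.0987 and 0.0662, 0.0502 and 0.0939) or either 222KO library (0.0626 and 0.0772). Among the lists, the calls of G1/S (adjusted p = 0.293), oxidative phosphorylation (0.169) and stress response genes (0.293) were lost without 221KO replicate 2. That of metallothioneins was lost without 221KO replicate 1 (0.224) or WT replicate 2 (0.117), that of oxidative phosphorylation without WT replicate 2 (0.124) and that of stress response genes without WT replicate 1 (0.196). List medians moved with single libraries. Without 221KO replicate 1 or 2 they were −0.60 and −0.10 for G1/S, −0.27 and −0.08 for stress response genes and 0.12 and 0.56 for metallothioneins. Metallothioneins were at 0.46 without WT replicate 1, and p53 targets were at −0.35 without 221KO replicate 1.

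Loss of miR-222 alone was compared with WT in the same way. LCP1 fell to 0.590 ± 0.0687 FPKM (log2 change −5.10, adjusted p = 1.22e-05), TFPI to 0.783 ± 0.111 (−5.26, 3.51e-06), CALB1 to 0.0317 (−5.28, 6.95e-06) and TM4SF19 to 0.238 (−5.07, 0.000141). HBE1 and OR51B5 were listed at 0 in both 222KO libraries, and MIR100HG fell by 5.02. EREG fell to 7.69 ± 0.143 (−3.48, adjusted p = 0.000293). CALB2 (calretinin) fell from 49.5 ± 9.67 to 1.41 ± 0.0792 and the chromatin protein HMGA2 from 11.9 ± 1.66 to 0.0803 ± 0.033, by 4.38 and 3.57. SAA1 rose from 17.1 ± 9.37 to 354 ± 8.19 (4.40, adjusted p = 0.0131) and SAA2 from 1.37 ± 0.476 to 32.9 ± 1.14 (3.85, adjusted p = 0.0317). The connexin GJC1 rose from 2.58 ± 0.643 to 18.5 ± 0.859, ADAM11 from 9.03 ± 0.505 to 53.1 ± 1.98 and the semaphorin receptor PLXNA2 to 13.4 ± 1.02, by 2.46, 2.43 and 2.32. VSTM1, the keratin KRT81, the actin regulator CALD1, MSN and OASL rose by 2.29, 2.26, 2.01, 2.37 and 1.88.

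In 222KO, 6 of the 37 interferon genes rose and 0 fell (10 and 1 adjusted over the list alone; median 0.48; camera adjusted p = 0.000838, and adjusted p = 0.849 with an estimated correlation), among them IFIT1, by 1.51, and HERC6, by 1.18. Of the NRF2 targets 4 fell (7 adjusted over the list alone; median −0.45; camera adjusted p = 0.00137, and adjusted p = 0.407 with an estimated correlation), among them SLC7A11, to 1.14 ± 0.0812. Of the oxidative phosphorylation genes 3 fell (4 adjusted over the list alone; median −0.12; camera adjusted p = 0.00135, and adjusted p = 0.827 with an estimated correlation), among them COX6C, a cytochrome oxidase subunit, by 0.44. Of 51 cytosolic ribosomal proteins, whose many processed copies make their values uncertain, 2 fell (2 adjusted over the list alone; median −0.19; camera adjusted p = 0.00137, and adjusted p = 0.849 with an estimated correlation), RPS7 by 0.93 and RPS13 by 0.55. Of the cholesterol genes 2 fell (3 adjusted over the list alone; median −0.17; camera adjusted p = 0.0107, and adjusted p = 0.827 with an estimated correlation). Of the metallothioneins 1 rose (3 adjusted over the list alone; median 0.41; camera adjusted p = 0.0271, and adjusted p = 0.827 with an estimated correlation). The ribosomal call was also lost with quantile normalization (median −0.10, adjusted p = 0.14) and without WT replicate 2 (0.184), and without that library those of cholesterol and metallothionein genes were lost too (both 0.122). Without WT replicate 1 the medians were −0.30 for cholesterol, −0.29 for ribosomal, 0.31 for interferon and 0.63 for metallothionein genes. Without WT replicate 2 that of ribosomal genes was −0.10, and without 222KO replicate 2 that of oxidative phosphorylation genes was −0.07.

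limma called 995 genes in 222KO against WT, 471 higher and 524 lower. The count was 633 with a 1.5-fold limit, 1639 without the filter, 187 with the 222KO libraries averaged to 1, 165 without 222KO replicate 1, 149 without 222KO replicate 2, 233 without WT replicate 1 and 394 without WT replicate 2. Calls of CALD1, KRT81, MSN, OASL, SAA1, SAA2 and VSTM1 were lost without 222KO replicate 1 (adjusted p = 0.114, 0.169, 0.0598, 0.152, 0.0986, 0.183 and 0.0822), 222KO replicate 2 (0.119, 0.183, 0.0701, 0.173, 0.115, 0.189 and 0.0828) or WT replicate 1 (0.0847, 0.0984, 0.0549, 0.131, 0.0816, 0.168 and 0.054). Those of KRT81, SAA2 and OASL were also lost without WT replicate 2 (0.125, 0.112 and 0.0573). The same held for the list members IFIT1, HERC6, SLC7A11, COX6C, RPS7 and RPS13 without 222KO replicate 1 (0.131, 0.0885, 0.067, 0.103, 0.131 and 0.096) or 2 (0.155, 0.0891, 0.0747, 0.18, 0.133 and 0.18). Without WT replicate 1, IFIT1, HERC6, COX6C, RPS7 and RPS13 were lost (0.0882, 0.069, 0.12, 0.0975 and 0.133).

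Loss of both microRNAs was compared with WT. EREG fell to 0.249 ± 0.15 FPKM (log2 change −6.29, adjusted p = 1.99e-05), ALDH1A3 to 5.11 ± 0.481 (−5.93, 4.13e-05), LCP1 to 0.163 ± 0.126 (−5.55, 9.36e-06) and TFPI to 0.575 ± 0.0968 (−5.44, 2.9e-06). HBE1 was listed at 0 in both libraries, and OR51B5, TM4SF19 and CALB1 fell, with log2 changes of −5.24, −5.07 and −4.86. The interferon-induced gene IFI27 fell from 47.7 ± 7.39 to 1.11 ± 0.872 (−4.59, adjusted p = 0.00553) and the retinaldehyde reductase DHRS3 from 37.9 ± 8.63 to 0.818 ± 0.135 (−4.40, 9.34e-05). SPINK6 rose to 248 ± 140 (7.02, adjusted p = 0.00151), MSN to 66.4 ± 18.8 (5.38, 0.000177) and DHRS2 from 45.6 ± 4.56 to 510 ± 49.3 (3.45, 3.91e-05). IL7R, an interleukin receptor chain, rose from 6.37 ± 2.34 to 68.9 ± 10.7 (3.28, adjusted p = 0.00383). SAA1, SAA2, NNMT, S100A4, OASL and IFI6 rose by 4.24, 3.07, 4.42, 3.69, 3.12 and 3.05.

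In DKO, 23 of the 37 interferon genes rose and 1 fell, IFI27 (28 and 1 adjusted over the list alone; median 1.27; camera adjusted p = 7.3e-14, and adjusted p = 0.596 with an estimated correlation). IFIT1 rose to 45.4 ± 1.19 FPKM, IFI44 to 60.9 ± 0.262 and DDX58 by 2.02. Of the p53 targets 9 fell (13 adjusted over the list alone; median −0.39; camera adjusted p = 4.53e-05, and adjusted p = 0.461 with an estimated correlation), among them MDM2, the ubiquitin ligase of p53, from 92.3 to 55.2 FPKM. The G1/S genes had a median of −0.40 (2 fell, 1 adjusted over the list alone; camera adjusted p = 1.5e-05, and adjusted p = 0.963 with an estimated correlation), with CDCA7 at 30.2 ± 1.96 FPKM. Of the histone genes 2 rose (6 adjusted over the list alone; median 0.71; camera adjusted p = 0.00038, and adjusted p = 0.555 with an estimated correlation). Of the metallothioneins 3 rose (4 adjusted over the list alone; median 0.84; camera adjusted p = 0.00201, and adjusted p = 0.555 with an estimated correlation), among them MT1F, to 26.4 ± 2.52. Of the cholesterol genes 4 fell (5 adjusted over the list alone; median −0.27; camera adjusted p = 0.000976, and adjusted p = 0.555 with an estimated correlation), FDFT1 to 50.6 ± 8.95. Of the NRF2 targets 7 fell and 1, HMOX1, rose (8 and 1 adjusted over the list alone; median −0.35; camera adjusted p = 0.014, and adjusted p = 0.461 with an estimated correlation).

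limma called 1554 genes in DKO against WT, 728 higher and 826 lower. The count was 922 with a 1.5-fold limit, 358 with only WT and DKO in the model, 436 without WT replicate 1, 741 without WT replicate 2, 677 without either 222KO library or with these averaged to 1, 571 without DKO replicate 1 and 580 without DKO replicate 2. Calls of SAA2, NNMT, IFI6, S100A4 and SAA1 were lost without WT replicate 1 (adjusted p = 0.204, 0.142, 0.0955, 0.0731 and 0.0663), those of the first 4 without DKO replicate 2 (0.128, 0.116, 0.106 and 0.0608). Those of SAA2, NNMT and IFI6 were lost without either 222KO library (0.103, 0.0689 and 0.0637), those of NNMT and IFI6 without DKO replicate 1 (0.0684 and 0.0869) and those of SAA2 and NNMT without WT replicate 2 (0.124 and 0.0834). Without WT replicate 1 the calls of MDM2, CDCA7 and FDFT1 were lost (0.0876, 0.065 and 0.0568), and without DKO replicate 1 as well (0.0981, 0.0563 and 0.0576). The call of MDM2 was also lost without DKO replicate 2 (0.0804) or either 222KO library (0.0631), and those of FDFT1 and CDCA7 without WT replicate 2 (0.0605 and 0.0501). HMOX1 lost its call without any 1 library of WT, 222KO or DKO, with adjusted p from 0.051 to 0.0866. Each of the 7 list calls in DKO was kept without each library. The G1/S median was −0.61 without DKO replicate 1 and −0.23 without DKO replicate 2 (adjusted p = 0.0463), and that of histone genes was 0.46 without DKO replicate 2.

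**Figure D2:**
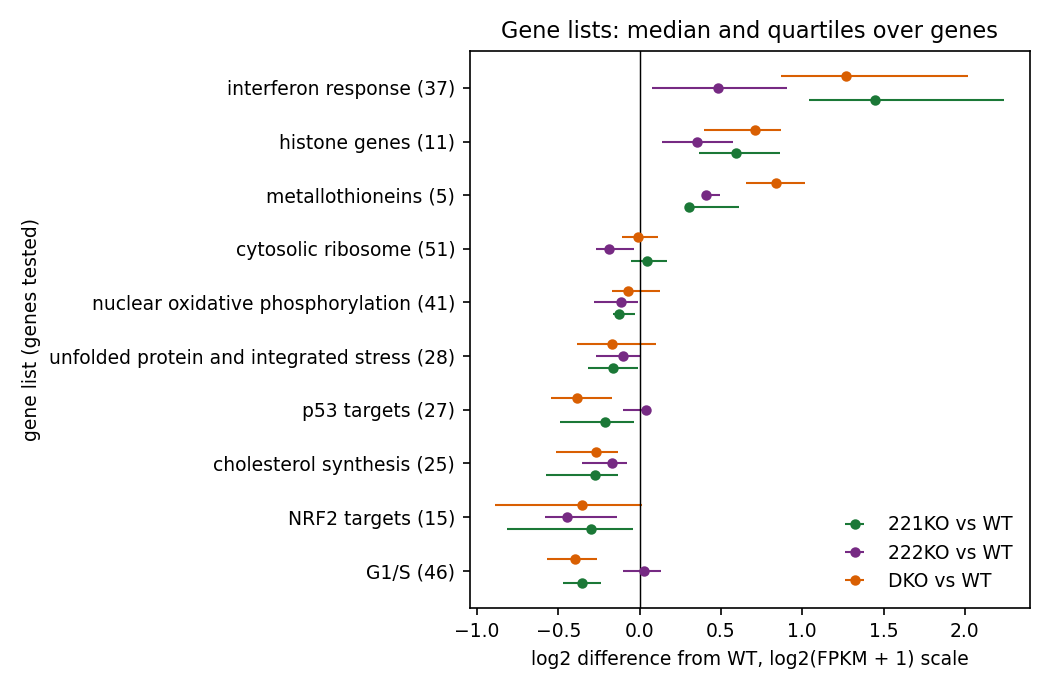
Points are medians and bars the lower to upper quartile, over the tested genes of each list called in at least 1 comparison, of the log2(FPKM + 1) difference of 221KO, 222KO and DKO from WT. The interferon response list had medians of 1.45, 0.48 and 1.27, and the G1/S list −0.36, 0.03 and −0.40.

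fry, which asks whether the genes of a list move one way on balance and does not set them against other genes, called 6, 5 and 7 lists in 221KO, 222KO and DKO, of which camera called 5, 1 and 5. The others were mesenchymal genes, higher in all 3 (fry adjusted p = 0.00737, 0.00545 and 0.000578), stress response genes, lower in 222KO (0.0455) and DKO (0.0341), and, higher in 222KO, microRNA machinery (0.00545) and YAP targets (0.029). Of the lists camera called, fry did not call G1/S (0.378), histone (0.0506), metallothionein (0.0716) or oxidative phosphorylation genes (0.109) in 221KO. In 222KO it did not call cholesterol synthesis (0.105), ribosomal protein (0.402), interferon (0.227), metallothionein (0.0786) or oxidative phosphorylation genes (0.0602). In DKO it did not call cholesterol synthesis (0.0613) or G1/S genes (0.359).

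The remaining lists had no call by camera in any knockout. Camera's adjusted p-values in 221KO, 222KO and DKO were 0.311, 0.965 and 0.964 for 30 epithelial genes, of which 4, 1 and 4 rose and 4, 2 and 4 fell (5, 1 and 4, and 5, 2 and 5 adjusted over the list alone). KRT18, a keratin with many processed copies, was among those that fell, from 1302 ± 40.3 FPKM to 599 ± 80.8, 538 ± 9.74 and 480 ± 56.8. The 8 mesenchymal genes (0.309, 0.404 and 0.0583) had 4, 2 and 3 that rose and 1, 0 and 1 that fell (4, 3 and 4, and 2, 0 and 2 adjusted over the list alone). Of 19 YAP targets (0.309, 0.207 and 0.468) 4, 3 and 4 rose and 2 in each fell (4, 6 and 5, and 2, 2 and 4 adjusted over the list alone). The receptor kinase AXL rose from 287 ± 13.9 to 503 ± 12.4, 427 ± 6.78 and 655 ± 14.1. Of 20 NF-kB genes (0.262, 0.439 and 0.561) 4 in each rose and 2, 0 and 3 fell (4 in each, and 2, 3 and 4 adjusted over the list alone). Of 22 TGF-beta targets (0.12, 0.152 and 0.964) 4, 0 and 1 rose and 2, 0 and 4 fell (6, 0 and 1, and 2, 0 and 5 adjusted over the list alone). Of 30 immediate early genes (0.143, 0.85 and 0.262) 3, 1 and 3 rose and 6, 1 and 5 fell (5, 4 and 5, and 10, 2 and 6 adjusted over the list alone).

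Of 20 FOXO targets (adjusted p = 0.733, 0.207 and 0.964) 2, 1 and 4 rose and 2, 3 and 4 fell (3, 1 and 4, and 3, 4 and 4 adjusted over the list alone). CITED2, a transcriptional coregulator, rose from 15.7 ± 1.09 FPKM to 64.6 ± 5.02, 22.7 ± 1.79 and 75.3 ± 3.34. Among 15 BCL2 family genes (0.824, 0.659 and 0.994) 2, 0 and 2 rose and 0, 1 and 0 fell (2 in each, and 0, 1 and 0 adjusted over the list alone). Of 20 genes of the microRNA machinery (0.53, 0.168 and 0.912) 1, 1 and 2 rose (1, 1 and 3, with 1 falling in DKO, adjusted over the list alone). Of 14 WNT targets (0.824, 0.843 and 0.912) 1, 0 and 1 rose and 0, 0 and 1 fell, the same counts as adjusted over the list alone. Of 29 glycolysis and hypoxia genes (0.497, 0.933 and 0.912) 1, 1 and 2 rose and 1, 0 and 2 fell (1, 1 and 2, and 0, 0 and 2 adjusted over the list alone). Of 17 class I histocompatibility genes (0.143, 0.628 and 0.452) 0, 0 and 0 rose and 1, 0 and 1 fell, as adjusted over the list alone. Of 54 G2/M genes (0.159, 0.954 and 0.912) 1 fell in 221KO and 0 in the others (0 in each adjusted over the list alone). G1/S (0.954), histone (0.0781), p53 (0.638) and stress response genes (0.0559) did not pass in 222KO, nor ribosomal proteins in 221KO (0.426) and DKO (0.964), nor oxidative phosphorylation (0.761) and stress response genes (0.107) in DKO. Median, mean and test of a list differed in sign only among lists without a call: BCL2, FOXO, glycolysis, WNT and locus neighbours in 221KO, epithelial, G1/S, G2/M, immediate early, p53 and WNT in 222KO, and BCL2, epithelial, ribosomal, glycolysis, microRNA machinery, TGF-beta and YAP in DKO. In 222KO, the calls of CITED2, AXL and KRT18 were lost without 222KO replicate 1 (adjusted p = 0.145, 0.0936 and 0.0614), 222KO replicate 2 (0.253, 0.116 and 0.0701) or WT replicate 1 (0.185, 0.0659 and 0.0538), and that of CITED2 without each other library. In 221KO that of KRT18 was lost without WT replicate 1 (0.0578).

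To ask how far the single knockouts overlapped, their differences from WT were set side by side. The genes lower in both included EREG, LCP1, TFPI, CALB1, TM4SF19, MIR100HG and PHGDH, and those higher in both included MSN, OASL, IFIT1, SAA1 and SAA2. limma called 225 genes higher in both and 313 lower in both, and 16 in opposite directions. Independent lists of these sizes would share 21.9 and 29.6, a value that leaves out the shared WT libraries. Simulated unchanged groups against the same WT libraries shared 0 and 0, but averaged 0.06 and 0.04 calls in 221KO and 222KO, so that this count could hardly come out otherwise and gives no measure of the overlap. Across genes the log2 differences correlated with r = 0.631 (rho = 0.618), against a mean of 0.503 in simulations without any effect (range 0.412 to 0.610; rho 0.457), and their covariance was 0.252 against a simulated 0.0837. Without 221KO replicate 1 or 2, r was 0.535 and 0.581, and without 222KO replicate 1 or 2 it was 0.556 and 0.559, all inside that range. Simulations with 1 library fewer, added after the values were seen, averaged r = 0.411 (range 0.292 to 0.525) and a covariance of 0.0834, beside observed covariances of 0.250 to 0.254. With a WT library of its own for each knockout, a choice made after the values were seen, r was 0.239 and the covariance 0.125 with WT replicate 1 for 221KO and replicate 2 for 222KO, and 0.339 and 0.165 the other way round. Each of these differences rests on 1 WT library. The orthogonal main effects of the microRNAs correlated with r = 0.237 (rho = 0.292), and genes are not independent replicates. Both effects use all 8 libraries, so their shared chance values cancel only if the groups vary alike. Median absolute log2 differences between replicates ranged from 0.0716 in 222KO to 0.193 in 221KO. A deviation of WT alone would also move both effects the same way, so this r is not free of shared chance.

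Against WT, 221KO and DKO shared 456 higher and 581 lower genes (33.8 and 46.7 for independent lists), with 0 in opposite directions, r = 0.753 and a covariance of 0.344. 222KO and DKO shared 214 and 307 (27.2 and 34.4), with 23 in opposite directions, r = 0.608 and a covariance of 0.254, beside the same simulated covariance of 0.0837. With separate WT libraries the covariances were 0.231 and 0.242 for 221KO and DKO, and 0.162 and 0.132 for 222KO and DKO. In all 3 knockouts 176 genes were higher and 273 lower.

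**Figure D3:**
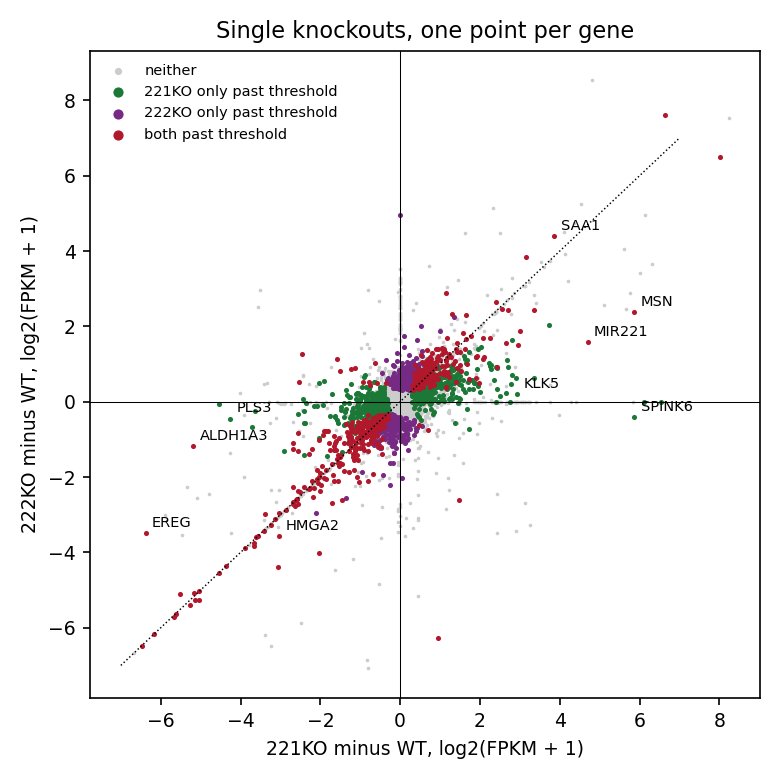
Each point is a tested gene, with its log2(FPKM + 1) difference of 221KO from WT on the x axis and of 222KO from WT on the y axis, coloured by which comparison passed the threshold; the dotted line marks equal differences. The 225 genes higher in both and the 313 lower in both lie in the upper right and lower left parts of the plot, and r over all 12588 genes was 0.631.

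The direct comparison of the single knockouts asked which genes differ between loss of 1 paralogue and loss of the other. ALDH1A3 was lower in 221KO (9.47 ± 2.78 FPKM) than in 222KO (164 ± 1.12; log2 difference −4.00, adjusted p = 0.000596), as was PLS3 (1.41 ± 0.107 against 32.5 ± 1.54; −3.80, 6.99e-05). The decoy death receptor TNFRSF10C (0.257 ± 0.0193 against 12.1 ± 0.288), DHRS3 (1.96 ± 0.26 against 23.0 ± 0.253) and EREG were also lower in 221KO, with log2 differences of −3.38, −3.02 and −2.90. Higher in 221KO were SPINK6 (111 ± 62.7 against 0.335 ± 0.271; 6.29, adjusted p = 0.00546), MSN (93.5 ± 22.8 against 7.24 ± 0.385; 3.50, 0.00272) and KLK5 (2.75, 0.00136). So were DHRS2 (289 ± 2.15 against 54.0 ± 0.224; 2.40, 0.000527) and the antiviral gene RSAD2 (13.2 ± 7.17 against 2.11 ± 0.357; 2.10, 0.046). limma called 477 genes, 194 higher and 283 lower in 221KO. The count was 297 with a filter at FPKM 5, 71 with only these groups in the model, 110 with the 222KO libraries averaged to 1, 87 without 222KO replicate 1, 90 without 222KO replicate 2, 215 without 221KO replicate 2 and 301 without either WT library. The call of SPINK6 was lost without 222KO replicate 1 (adjusted p = 0.0528) or 2 (0.0639), and that of RSAD2 without 222KO replicate 1 (0.288) or 2 (0.229), 221KO replicate 2 (0.0854), either WT library (0.099) or either DKO library (0.081).

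Loss of miR-222 on top of loss of miR-221 was read from DKO against 221KO. HMGA2, at 0.578 ± 0.0831 FPKM in 221KO, was higher in DKO (9.45 ± 0.343; log2 difference 2.73, adjusted p = 0.00103), as was the semaphorin and growth factor coreceptor NRP1 (1.34 ± 0.254 against 12.4 ± 1.23; 2.51, 0.00121). Their WT levels were 11.9 ± 1.66 and 9.59 ± 0.311. MIR100HG, listed at 0 in 221KO, held 4.02 ± 1.61 in DKO (adjusted p = 0.0386). AADACL3 (6.00 ± 0.569 against 0.269 ± 0.0974) and SMIM22 (20.8 ± 5.03 against 1.43 ± 0.69) were lower in DKO (log2 differences −2.46 and −3.17), as was PDP1, a phosphatase of pyruvate dehydrogenase (−0.93), and PDCD6 was higher (124 against 219; 0.81). TSPAN5, SCML1, KIAA1462, PNMA2 and the cytokine IL11 were higher by 1.38, 1.20, 1.26, 1.12 and 1.05. limma called 18 genes, 11 higher and 7 lower, of which 6 were small RNA entries on few fragments; 789 genes had an unadjusted p under 0.05. Replicates 1 of both groups against replicates 2 gave 369 calls. The count was 30 with a pseudocount of 0.1, 31 without the filter, 37 and 30 without 221KO replicate 1 or 2, 35 and 40 without DKO replicate 1 or 2, and 11 without either WT library. The balance of directions moved with it: 13 higher and 17 lower with a pseudocount of 0.1, 13 and 24 without 221KO replicate 1, 7 and 23 without 221KO replicate 2, 23 and 12 without DKO replicate 1, and 32 and 8 without DKO replicate 2. Without 1 library, 8 to 15 of the 18 genes were called again. Of the 12 genes other than small RNA entries, HMGA2, NRP1 and AADACL3 kept their calls without each library. IL11 and PDCD6 lost theirs without any 1 library (adjusted p = 0.0643 to 0.155 and 0.0616 to 0.0974), and PDP1 without any but DKO replicate 2 (up to 0.159). MIR100HG lost its call without any 1 library of WT, 221KO or 222KO (up to 0.174). SMIM22 and PNMA2 lost theirs without any 1 library of WT or 222KO or without 221KO replicate 2 (up to 0.107 and 0.0786). The call of KIAA1462 was lost without any 1 library of WT or 222KO (up to 0.0868), that of SCML1 without either 222KO library (0.0586) and that of TSPAN5 without DKO replicate 1 (0.0512).

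Loss of miR-221 on top of loss of miR-222, read from DKO against 222KO, gave 764 called genes, 335 higher and 429 lower in DKO. CDKN1B and CDKN1C were among those higher, and EREG, PLS3 and ALDH1A3 stood at 0.249, 2.90 and 5.11 FPKM in DKO beside 7.69, 32.5 and 164 in 222KO. The count was 142 with the 222KO libraries averaged to 1, 386 with only these groups in the model, 127 without 222KO replicate 1, 117 without 222KO replicate 2, 272 without DKO replicate 1, 270 without DKO replicate 2 and 489 without either WT library.

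The interaction asked where DKO departed from the sum of both single differences. HMGA2 (log2 6.30, adjusted p = 3.05e-05) and MIR100HG (7.31, 0.00028) were low in both single knockouts and higher in DKO. Because FPKM ends at 0, their interactions would still be 2.91 and 5.02 with DKO at 0, and with pseudocounts of 5 and 0.1 they were 3.10 and 9.88 for HMGA2 and 3.71 and 13.55 for MIR100HG. The collagen COL4A1 stood at 2.87 ± 0.858 FPKM in WT, 12.3 ± 5.9 in 221KO, 8.57 ± 0.28 in 222KO and 2.53 ± 0.593 in DKO, an interaction of −3.17 (adjusted p = 0.0327). The DNA sensor IFI16 (−2.64, 0.0499), PLXNA2 (−2.64, 0.00935), GJC1 (−2.67, 0.00493) and MSN (−2.87, 0.0152) also had negative interactions. For CALB1 (5.47), HBE1 (5.67) and OR51B5 (5.44) all 3 knockouts lay near 0, and the value with DKO at 0 would be 5.01, 5.67 and 5.28. limma called 358 genes, 215 positive and 143 negative. The count was 198 with a filter at FPKM 5, 821 without the filter, 143 with the 222KO libraries averaged to 1, 119 and 110 without 222KO replicate 1 or 2, 169 and 174 without DKO replicate 1 or 2, and 174 and 194 without WT replicate 1 or 2. Calls of COL4A1, IFI16, MSN and PLXNA2 were lost without 222KO replicate 1 (adjusted p = 0.148, 0.201, 0.0911 and 0.055), 222KO replicate 2 (0.169, 0.21, 0.0975 and 0.0681), WT replicate 1 (0.129, 0.167, 0.0813 and 0.0563) or WT replicate 2 (0.0808, 0.109, 0.0703 and 0.051). COL4A1 and IFI16 lost theirs also without DKO replicate 1 (0.112 and 0.136) or 2 (0.0899 and 0.0942), and IFI16 without 221KO replicate 2 (0.0747).

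MicroRNAs lower messenger RNAs with seed sites in the 3' UTR, and miR-221-3p (AGCUACAUUGUCUGCUGGGUUUC) and miR-222-3p (AGCUACAUCUGGCUACUGGGU) share the site ATGTAGC. Genes were counted as having a site where the 3' UTR held ATGTAGC or the other 7-base form, TGTAGCA. The 1865 tested genes with a site differed from 9338 genes without one by a median log2 change of −0.0012 in 221KO, 0.019 in 222KO and 0.0086 in DKO. camera did not call these differences (adjusted p = 0.914, 0.811 and 0.914 over the 27 site tests run, and adjusted p = 0.95 for each with an estimated correlation). Among the 630 permuted sites, whose median differences were −0.0231, 0.00269 and −0.0288, the real site ranked 42, 34 and 9 from the highest. The difference in 221KO was 0.024 without WT replicate 1, and without WT replicate 2 those in 222KO and DKO were −0.0041 and −0.024, so the sign against genes without a site was not settled. The difference stayed above the median of the permuted sites without each library, with ranks of 21 to 96 in 221KO, 9 to 63 in 222KO and 2 to 29 in DKO. The lowest ranks came without WT replicate 1 and the highest without WT replicate 2. The 1017 tested genes with ATGTAGC itself differed by −0.0085 in 221KO, 0.0141 in 222KO and 0.0091 in DKO against WT (camera adjusted p = 0.914 for each). Genes with an 8-base site (400 genes) differed by 0.048 in DKO against WT (adjusted p = 0.711). In DKO against 221KO the same genes differed by 0.030 (p = 0.00343 and adjusted p = 0.0925, with p = 0.198 and adjusted p = 0.95 with an estimated correlation). All site genes differed there by 0.0097 (camera adjusted p = 0.75, rank 3 of 630). In DKO against 222KO all site genes differed by −0.019 (camera adjusted p = 0.9, rank 42) and those with an 8-base site by 0.0045 (camera adjusted p = 0.914). Between 221KO and 222KO the difference of all site genes was −0.031 (camera adjusted p = 0.711, rank 450). Genes with sites for the 5p arms differed by 0.027 for miR-221-5p in 221KO (3243 genes, adjusted p = 0.811) and −0.010 for miR-222-5p in 222KO (2346 genes, adjusted p = 0.914).

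The paralogues differ outside the seed, so sites with further pairing to 1 of them were compared between the single knockouts. In 221KO against 222KO, 70 genes with miR-221-type pairing had a mean log2 difference of 0.08 and 27 genes with miR-222-type pairing −0.12. The difference of means was 0.20, with p = 0.0531 by a two-sided permutation test with 100000 resamples, which did not pass.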

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

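Of the tests in this part, the exchange of libraries between 221KO and DKO was set out beforehand, and those of the spread and of shared losses were chosen after the result was seen. The difference between losing a microRNA in WT cells and losing it where the other was already lost was tested for each gene as the interaction, and 358 genes passed. Among the genes the naming rule took, it was positive for HMGA2 (log2 6.30), MIR100HG (7.31), CALB1 (5.47), HBE1 (5.67) and OR51B5 (5.44), and negative for COL4A1 (−3.17), GJC1 (−2.67), IFI16 (−2.64), MSN (−2.87) and PLXNA2 (−2.64). FPKM ends at 0, and the single knockouts of the 5 genes with positive values were already near it. With DKO at 0 the interaction would be 5.01 for CALB1, 5.67 for HBE1, 5.28 for OR51B5, 5.02 for MIR100HG and 2.91 for HMGA2. Small RNA entries passed as well, with MIR3143 at 6.47, MIR4685 at 6.41, MIR6882 at 6.17, MIR1226 at −5.55, MIR1249 at −6.12, MIR6742 at −6.53, MIR6764 at −7.54 and SNORD18C at −7.62. Where above 0, these 8 entries held 1 to 4 times their own smallest value, so their levels are few whole steps on very short transcripts. HMGA2 stood at 11.9 FPKM in WT, 0.578 in 221KO, 0.0803 in 222KO and 9.45 in DKO, and MIR100HG at 31.8, 0, 0.00504 and 4.02.

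DKO lay close to 221KO, with 18 genes called between them (12 of them other than small RNA entries) against 764 between DKO and 222KO. The group means lay close as well, with a median absolute log2 difference of 0.0852 for DKO against 221KO and 0.176 for 222KO against WT. These values do not measure the spread within groups. Replicates differed more within 221KO (median absolute log2 difference 0.193) and DKO (0.161) than within WT (0.147) or 222KO (0.0716). Calls missed because of this larger spread therefore stay open. Exchanged labels stay open: of the 2 ways to exchange 1 library of each group, 1 gave 7 calls (0 without small RNA entries) and the other, replicates 1 against replicates 2, 369 (352), so an exchange cannot be told apart from a structure of the samples that follows the replicate number. Of 37 genes at or below 10 percent of WT in 221KO, 83.8 percent were also lost in DKO and 1 was back above 50 percent. This share is not particular to the pair: of 30 genes lost in 222KO, 25 were also lost in 221KO. In all 3 knockouts 23 genes were lost. DKO cells derived from the 221KO line and an effect of miR-221 loss present in both would each give losses shared by 221KO and DKO. These cannot be told apart, because no label says how the DKO line was made or whether the libraries of a genotype came from separate lines.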

How the results depend on the processing

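Averaging the 222KO libraries, leaving out small RNA entries, separate WT libraries for the single knockouts and other limits for genes detected in WT only are tests chosen after the result was seen; the other alternatives were planned. Where no reason is given, the cause was not tested. With a 1.5-fold limit 794 genes were called in 221KO, 633 in 222KO and 922 in DKO against WT, since low folds are excluded by construction. With only the compared groups in the model the counts were 160 in 221KO and 358 in DKO against WT, 71 in 221KO against 222KO and 386 in DKO against 222KO. With the 222KO libraries averaged to 1 they were 473, 187 and 677 against WT, 110 in 221KO against 222KO, 142 in DKO against 222KO and 143 for the interaction. Without the filter 1639 genes were called in 222KO against WT, 31 in DKO against 221KO and 821 for the interaction, and with a filter at FPKM 5 the counts were 297 in 221KO against 222KO and 198 for the interaction. A pseudocount of 0.1 gave 30 calls in DKO against 221KO. Leaving out 1 library gave 357 to 954 calls in 221KO, 149 to 972 in 222KO and 436 to 1646 in DKO against WT, 87 to 346 in 221KO against 222KO, 110 to 266 for the interaction, 11 to 40 in DKO against 221KO and 117 to 772 in DKO against 222KO. Leaving out a 221KO library raised the count in DKO against WT. No scaling moved the share of higher calls by over 10 percentage points or the median of all genes by over 0.1, and the counts under trend and robust options, median-of-ratios scaling, quantile normalization, a pseudocount of 5 and without small RNA entries lay within 1.5 times those reported.

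With an estimated correlation 0 of the 9 lists in 221KO, 0 of the 6 in 222KO and 0 of the 7 in DKO were called. The correlation of the single knockouts was 0.535 to 0.731 without 1 library, the highest without WT replicate 2. It was 0.239 and 0.339 with separate WT libraries, where no library enters both differences. The seed site difference in 221KO turned positive with 8-base sites (0.0031), in strata of 3' UTR length (0.0049), with site genes at FPKM 5 (0.0052) and with quantile normalization (0.00085), and ranged from −0.033 to 0.024 without 1 library. In 222KO it ranged from −0.0041 to 0.052 and in DKO from −0.024 to 0.035, turning negative in both without WT replicate 2; none of these differences had passed. Genes detected in WT only numbered 23 with a limit of 10 percent, 11 with an FPKM of at least 10 in WT, and 17 to 21 without 1 library. Of 286 single named results that were called, 0 turned in direction under any alternative, and 50 of those not called changed sign under at least 1. A pseudocount of 0.1 moved the log2 change of 56 called results by over 1.5 times and one of 5 that of 102. Median-of-ratios scaling ended 1 call, quantile normalization 7, a pseudocount of 0.1 or 5 ended 7 or 12, no filter 18, a model of the compared groups alone 122, and leaving out WT replicate 1 ended 138. The sample names number all replicates 1 before all replicates 2, with the groups in the same order each time. No label says what this order stands for, so the main model did not treat the libraries as pairs. Correlations of the replicate differences between groups ranged from −0.0126 to 0.174, with 3 of 6 above 0.1. These 3 were WT with 221KO (0.112), WT with DKO (0.138) and 221KO with DKO (0.174). A structure that follows the replicate number in these groups therefore stays open. The replicate block gave 2545, 1799 and 2930 calls in 221KO, 222KO and DKO against WT, 863 in 221KO against 222KO, 732 for the interaction and 1487 in DKO against 222KO, 18 in DKO against 221KO, and 9, 8 and 7 called lists. With it 41 named results passed that had not, among them CDKN1C in 221KO (adjusted p = 0.0462) and KDM6A in 222KO (0.0486). A count-based alternative with other size factors was not run, because the table holds FPKM. Depth limits the short hairpin and small RNA entries, which rest on few fragments, and genes near an FPKM of 1, where the added 1 shrinks a fold change.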

Other observations

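Of the tests in this part, those of chromosomal neighbours and of the stretch shared by the hairpins were set out beforehand, and those of other cell types, single segments, separate drift, shared losses, locus neighbours and hairpin ratio were chosen after the result was seen. Leaving out small RNA entries, a group of genes was on in WT and off in all 3 knockouts: 17 genes had an FPKM of at least 5 in both WT libraries and at most 5 percent of the lower one in each of the 6 knockout libraries. Besides HBE1, OR51B5, LCP1, TFPI, CALB1, TM4SF19 and PHGDH, they were the cell cycle inhibitor CDKN2A (11.9 ± 0.131 FPKM in WT, highest knockout library 0.0917), the cyclin CCND2 (6.02 ± 0.698, 0.113), the transcription factor NFIB (6.31 ± 0.457, 0.0135), the colon cancer transcripts CCAT1 (10.2 ± 2.46, 0.0358) and CASC19 (15.0 ± 3.7, 0.253), the trypsinogen PRSS3 (8.64 ± 0.6, 0.053), GLMP (12.6 ± 0.836, 0.107), ERICH5 (7.71 ± 0.477, 0.153), the pseudogene AADACP1 (7.89 ± 2.42, listed at 0) and the olfactory receptor OR51B4 (10.9 ± 0.278, listed at 0). HBE1, OR51B5 and OR51B4 have overlapping or adjacent annotation on chromosome 11 (5268345 to 5505652, GRCh38), so these may not be separate genes' fragments; the count was 23 with a limit of 10 percent. Chance alone places 2 given libraries highest of 8 in 3.57 percent of genes. That rate concerns rank alone and gives no measure for the far wider gap required of these genes.

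Other on and off patterns were rare among the same genes. EREG, MYL9 and TNFRSF10C were on in WT and 222KO and off in 221KO and DKO, SPINK6 was on in 221KO and DKO alone, and each of the other patterns held 0 genes. EREG met the limit of FPKM 5 in 222KO but had fallen there against WT, with log2 changes of −3.69 to −3.00 over all alternatives. Of the small RNA entries left out of these counts, 15 met the same rule in some pattern, 5 of them on in WT alone. The myosin light chain MYL9 read 5.13 and 5.22 FPKM in WT, 14.4 and 13.2 in 222KO, 0.141 and 0.112 in 221KO and 0.0363 and 0 in DKO. DLC1 fell from 52.1 ± 2.17 FPKM in WT to 8.09 ± 1.33 in 221KO, 28.7 ± 0.441 in 222KO and 3.19 ± 0.183 in DKO (log2 changes −2.55, −0.84 and −3.66; limma adjusted p = 0.000186, 0.015 and 4.34e-05). Its 222KO call was lost without either WT library (0.0959 and 0.0646) or either 222KO library (0.108 and 0.126). SNAI2, a transcription factor of epithelial to mesenchymal transition, read 10.9 ± 0.135 in WT, 2.36 ± 1.67 in 221KO, 16.5 ± 0.241 in 222KO and 2.38 ± 0.81 in DKO, and fell in 221KO (adjusted p = 0.0284) and DKO (0.0279). Without WT replicate 1 these calls were lost (0.151 and 0.142), as without WT replicate 2 (0.106 and 0.107) or either 222KO library (0.0811 and 0.076). SDHA, a subunit of complex II with transcribed copies in the genome, rose in DKO from 69.8 ± 7.71 to 179 ± 10 FPKM (adjusted p = 0.0014).

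For the 17 genes on in WT only, RNA of leukocytes, red cells, fibroblasts or endothelial cells in the WT cultures is argued against, since 38 markers of these cells had a median of 0.00345 FPKM in WT beside 12.6 for the genes themselves; PTPRC and HBB were listed at 0, and of the 4 markers at FPKM 1 or more, CD68, ACTA2, TAGLN and COL1A1, 0 exceeded every knockout library by more than 2 times. Loss of wide chromosomal segments as the source of the whole group is argued against by 62 expressed neighbours within 500 kb of 13 genes, 22 of them around GLMP, whose median log2 difference was −0.0152 (SD 0.273, 0 at or below −1; −0.0922 with each gene weighted alike). Loss of a wide segment stays open for 6 genes. TFPI, NFIB and CASC19 had no such neighbour, and CCAT1 had no position in the annotation used, so its neighbours were not searched. The only one of CDKN2A, MTAP, lay at −0.78, and those of LCP1, ZC3H13 and LRCH1, at −0.34 and −0.59. For the other 11, the neighbours cannot exclude a loss confined to the gene itself. Of these, AADACP1 had 1 neighbour, and HBE1, OR51B4 and OR51B5 had only the same 1, TRIM5. Separate drift of each knockout line, with every gene equally prone to loss, is argued against as the source of the shared losses. In all 3 lines 23 genes were at or below 10 percent of WT. Independent losses among the 9084 genes on in WT would share 0.000471 (highest of 10000 draws 1). Equal proneness was assumed and not tested, and losses limited to as few as 41.1 genes would share as many. Drift that favours certain genes therefore stays open, as does separate drift for the 13 lost in 1 line alone. An ancestor cell shared by the knockout lines, which may underlie part of the genes that the single knockouts share, cannot be told apart from loss of either microRNA: both predict the 17 shared losses, and no label gives independent lines of a genotype.

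The MIR221 hairpin read higher in 221KO and DKO, with 403 and 665 fragments over both libraries beside 15 in WT and 47 in 222KO. Fragments of MIR222 counted on MIR221 are argued against, because the longest stretch the 2 hairpins share is 9 bases of 110. Higher transcription of the whole neighbourhood is argued against as well, since 7 tested neighbours had a median log2 change of 0.0203 in DKO (SD 0.207, highest 0.377). The highest was KDM6A, which had passed in 221KO and DKO. MIR222HG, the host gene of both hairpins, was not analysed, so higher transcription of the host alone stays open. A candidate explanation is a primary transcript no longer cut at an edited hairpin, so that it stays in the poly(A) RNA. In DKO the MIR222 fragments were 0.902 percent of those of MIR221 (6 against 665), which such a transcript with both hairpins present would not give, but it cannot be told apart from a deletion of MIR222 sequence because the extent of the edits was not given.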
